A study of Mus musculus with 17 samples.

How the data were processed

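RNA of EDL muscle from 17 mice was sequenced after library preparation with an Illumina TruSeq v2 kit, per the labels' protocols. Reads were aligned to mm10, per the submitters' processing notes, and the table was exported from a RefSeq-based re-alignment, per the file headers. The aligner, the counter, their versions and whether strand was used are not given in the sources used here. The deposited table holds 36172 rows, 1 per gene locus, with coordinates. It has estimated counts for each sample, deposited by the authors without scaling for depth, and only 25.5% to 29.3% of the values above 0 are whole within 0.001. The authors also deposited normalized log2 values, which equal log2 of the estimated counts times 1 factor per sample, minus a baseline per gene; how the factor was chosen is not given in the sources used here. Of the rows, 16061 were 0 in all 17 samples and 454 shared a symbol with another row and were kept apart. No row lies on the mitochondrial chromosome, so that genome was not analysed here.

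Samples were grouped by the vector named in their labels, and replicate numbers follow accession order and pair no animals. No 2 libraries agreed within sampling noise: the closest pair had a mean chi-square of 3.57 per gene, where 1 is expected from sampling. Estimated counts were rounded to whole numbers. Genes were kept by edgeR's filterByExpr with vector and sex as groups, which left 13965, scaled by trimmed mean of M values (TMM), and tested with edgeR 4.0.16 (R 4.3.3) by robust quasi-likelihood F tests. The comparison of vectors and that of sexes came from a model with both terms, and those within each sex and their difference from a model with 4 vector-by-sex groups. P-values were adjusted by the Benjamini-Hochberg method at 5%. The SE of a log2 fold change is its size divided by the square root of F, and intervals are 95%. CPM are TMM-scaled. Intervals and floors cover what the counts and animals show, and libraries carried no molecular identifiers.

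Before the data were examined, 42 gene lists were fixed for nerve, muscle, metabolism, immune, matrix and stress genes, and 40 with at least 3 measured members were tested, with the sex-check list kept out. Lists were tested on voom values with limma 3.58.1 by camera at a preset correlation of 0.01, and again with an estimated correlation and by fry. List medians come from the voom fit, while counts of members higher or lower come from the edgeR fit. In the comparison of vectors 3 lists have a median, a mean and a test that differ in sign, and in that of sexes 9 do. Named genes were also fixed by rule before the data were examined. Named were up to 10 genes past the threshold in each direction by smallest p for the comparison of vectors and 5 in each direction for the others (5 where none passed), a fixed panel of nerve, atrophy and myosin genes whatever their p, and up to 4 genes per list by smallest p; the text names part of these, and some genes are not reported here. Predicted genes were named only among the 3 smallest p.

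The procedure was tested on simulated counts drawn from the real means and library sizes. It recovered 67.2%, 94% and 100% of 1.5-fold, 2-fold and 4-fold changes between sexes, with 10 false calls among 13850 genes. Within females it recovered 61.2%, 83.6% and 100% and within males 49.3%, 77.6% and 95.5% of such changes between vectors, with 17 and 6 false calls among 13845 genes. Alternatives were DESeq2 1.42.0, other scalings, limma-voom with quality weights, no or a stricter filter, an age term, single ages, 1 surrogate variable from sva 3.50.0 and leaving out each animal. Gene tests used counts, so the pseudocount alternative planned for normalized values was not run. The exact test of Hand2 used log2(CPM + 0.1), and list scores used log2 CPM with a prior count of 2.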

Results

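Extensor digitorum longus (EDL) muscle, a fast-contracting muscle of the lower leg, was profiled by RNA sequencing in 17 aged mice. The design lists 10 animals given an empty vector (5 females, 5 males) and 7 given a Hand2 vector (4 females, 3 males). When, where and how the vectors were given is not stated in the labels. Hand2 is a transcription factor of sympathetic neurons, and the series title names the preservation of those neurons and the prevention of age-related muscle loss as its subject. The labels give an age of 22 months for 3 empty-vector and 4 Hand2 animals and 23 months for 7 and 3. The only males of 22 months are empty-vector replicate 10 and Hand2 replicate 4. The only females of 23 months are empty-vector replicates 3, 4 and 5 and Hand2 replicate 5. The 4 Hand2 animals of 22 months are also the 4 whose sample titles lack the sex letter that the other titles carry, so within the Hand2 group age and title form cannot be told apart. Total estimated counts per library ran from 19181208 to 30942818 with a median of 26091234, and averaged 26610484 ± 2717081 in the empty-vector group (SD, n = 10) and 24947159 ± 4435290 in the Hand2 group (SD, n = 7). A count of 3 corresponds to 0.097 to 0.156 CPM (counts scaled to library size) in these libraries. Each library is a separate animal, so p-values of gene tests and of permutations of animals measure the spread between these animals. Those of lists at camera's preset correlation do not. They compare a list's genes with the other genes and take the genes as nearly independent.

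The Hand2 transcript (Entrez gene 15111, chromosome 8, 57320983 to 57324517, plus strand, mm10) was higher in the Hand2 group in every animal. It averaged 0.440 ± 0.253 CPM with the empty vector (SD, n = 10) and 6.50 ± 9.30 CPM with the Hand2 vector (SD, n = 7). The highest empty-vector library held 0.94 CPM and the lowest Hand2 library 1.02 CPM, so the groups did not overlap. A two-sided exact permutation test on log2(CPM + 0.1) over 19448 splits gave p = 5.14e-05, the smallest those splits can give. Within females the exact test gave p = 0.00794 over 126 splits, and within males p = 0.0179 over 56 splits, again the smallest possible values. Spread within the Hand2 group was wide, with Hand2 replicate 7 at 26.3 CPM and the next library at 10.2 CPM. The counts do not separate transcripts made from the vector from those of the animals' own gene. Sex labels matched the libraries: Xist, the transcript of the inactive X chromosome, lay between 120 and 135 CPM in females and at or below 0.344 CPM in males, and Y-linked Ddx3y lay between 89.8 and 112 CPM in males and at or below 0.0863 CPM in females.

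**Figure D1:**
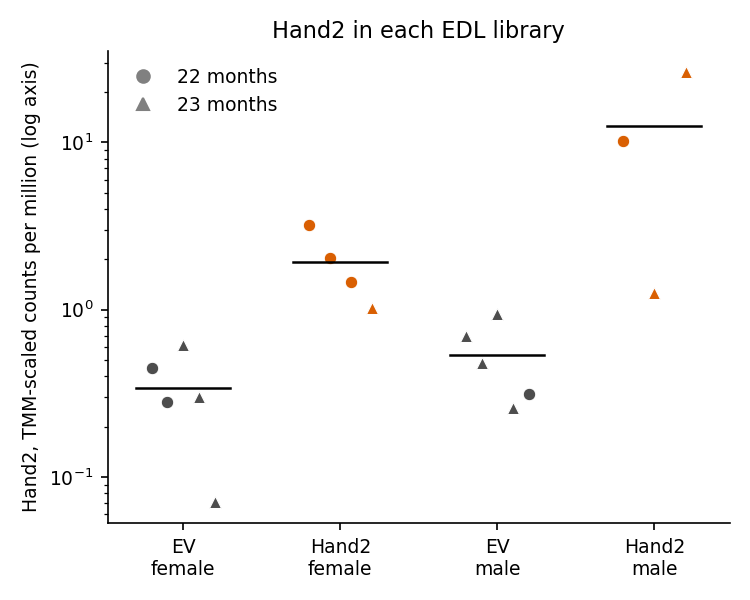
Hand2 in each library in TMM-scaled CPM on a log axis, by vector and sex, with circles for 22 and triangles for 23 months and bars at the arithmetic group mean. The lowest Hand2 library, at 1.02 CPM, lies above the highest empty-vector library, at 0.94 CPM.

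The first comparison asks what the Hand2 vector changed in the muscle transcriptome with sex taken into account. Among 13965 genes tested, 0 passed a 5% false discovery rate in edgeR's quasi-likelihood test. An unadjusted p under 0.05 was found for 705 genes, where 698 are expected by chance. DESeq2 called 1 gene, Hand2, and limma-voom with quality weights called 0 (844 genes at an unadjusted p under 0.05), as did limma on the authors' normalized values. Hand2 itself had the smallest p, with a log2 fold change of 3.63 ± 0.57 (SE, 95% interval 2.43 to 4.83) and an adjusted p = 0.124 in edgeR. DESeq2 gave 3.52 ± 0.57 with an adjusted p = 8.48e-06, and over the other settings the adjusted p ran up to 0.999, in males fitted alone. Without Hand2 replicate 6 edgeR's adjusted p for Hand2 was 0.0081. Adjusted over the list alone, Hand2 was the 1 gene that passed among the measured members of 40 fixed gene lists. In simulated counts of the same depth and group sizes this test recovered 74.6% of 1.5-fold, 97% of 2-fold and 100% of 4-fold changes, with 9 false calls among 13845 genes. The simulated changes were made together in many genes of higher expression, drawn independently and without shared differences between animals. Recovery in the real animals may therefore be lower, and Hand2 itself did not pass in edgeR.

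After Hand2, the genes with the smallest p were Matk, a kinase of blood cells (log2 fold change 1.21 ± 0.28), Hmha1 (0.49 ± 0.12), Mettl20 (0.27 ± 0.06) and the tight-junction gene Cldn4 (0.96 ± 0.24) on the higher side. On the lower side they were Ext1, a heparan sulfate polymerase (-0.23 ± 0.06), Hspbp1 (-0.16 ± 0.04), the splicing factor U2af1 (-0.19 ± 0.05), Mphosph6 (-0.30 ± 0.08) and the kinase gene Rps6ka3 (-0.37 ± 0.10). All 9 had an adjusted p = 0.921, so none passed.

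Neural and denervation genes did not separate the groups gene by gene. Th and Dbh, the enzymes of noradrenaline synthesis, did not pass the low-count filter. Th had 41 counts in 10 empty-vector and 10 in 7 Hand2 libraries, and Dbh had 15 and 34. With no filter, a reading chosen after the data were seen, edgeR gave -1.51 ± 0.84 for Th (interval -3.24 to 0.23) and 1.62 ± 0.65 for Dbh (interval 0.27 to 2.97), each with an adjusted p = 0.85. Of the sympathetic-neuron list 9 of 20 members were measurable, with a median log2 fold change of 0.01 (adjusted p = 0.384). With so few counts and measurable members, these muscle libraries do not show whether sympathetic neurons were preserved. The list of genes that respond to denervation was lower with Hand2 (median -0.17, 27 of 34 members lower) at camera's preset correlation (adjusted p = 6.3e-05) and did not pass with the correlation estimated (adjusted p = 0.473 with an estimated correlation). Its members include Myog, a myogenic factor induced when muscle loses its nerve (-0.99 ± 0.38, interval -1.79 to -0.19), Ankrd1 (-0.95 ± 0.31), Runx1 (-0.66 ± 0.35) and Chrna1, the acetylcholine receptor alpha subunit (-0.15 ± 0.12). Without empty-vector replicates 3, 4 and 5, 2 of which were high in immediate-early genes and 1 in interferon genes, that list's median was -0.07 and it did not pass (adjusted p = 0.265). Among 22-month animals the median of the denervation list was -0.142 and among 23-month animals -0.05. The adrenergic list had a median of -0.04 (adjusted p = 0.419), with Adra1d, an alpha-adrenergic receptor, at -0.51 ± 0.16. The neuromuscular-junction list had a median of -0.01, with 16 members higher and 17 lower (adjusted p = 0.603).

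Atrophy and fibre-type genes were near equal or imprecise over all animals. The atrophy list had 16 members higher and 16 lower, and its ubiquitin ligases Fbxo32 (0.14 ± 0.17) and Trim63 (0.01 ± 0.22) had 95% intervals of -0.21 to 0.49 and -0.46 to 0.48. The median of the atrophy list was 0.149 among 22-month and -0.094 among 23-month animals. That list was called at the preset correlation without empty-vector replicates 3, 4 and 5. The myosin heavy chains of fast fibres gave -0.14 ± 0.13 for Myh1, -0.30 ± 0.23 for Myh2 and 0.09 ± 0.09 for Myh4, and slow Myh7 gave 0.57 ± 0.68, a direction that turned to -0.78 in limma-voom. These myosin genes share similar sequence, and whether and how reads were divided among them is not given in the sources used here. Slow-fibre genes had a median of -0.30 in limma-voom (adjusted p = 0.00526; adjusted p = 0.813 with an estimated correlation), while in edgeR 8 members were higher and 9 lower with a median of -0.045. The list was at -0.77 among 22-month animals and 0.17 among 23-month animals, and it did not pass without Hand2 replicate 1 (adjusted p = 0.0745) or 2 (adjusted p = 0.281) or without a sex term (median -0.03, adjusted p = 0.497). Ppargc1a, a regulator of mitochondrial genes, was at -0.17 ± 0.12, and oxidative-phosphorylation genes had 75 of 79 members lower by a median of -0.05 (adjusted p = 5.11e-06; adjusted p = 0.813 with an estimated correlation), at -0.16 among 22-month animals and 0.015 among 23-month animals.

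**Figure D2:**
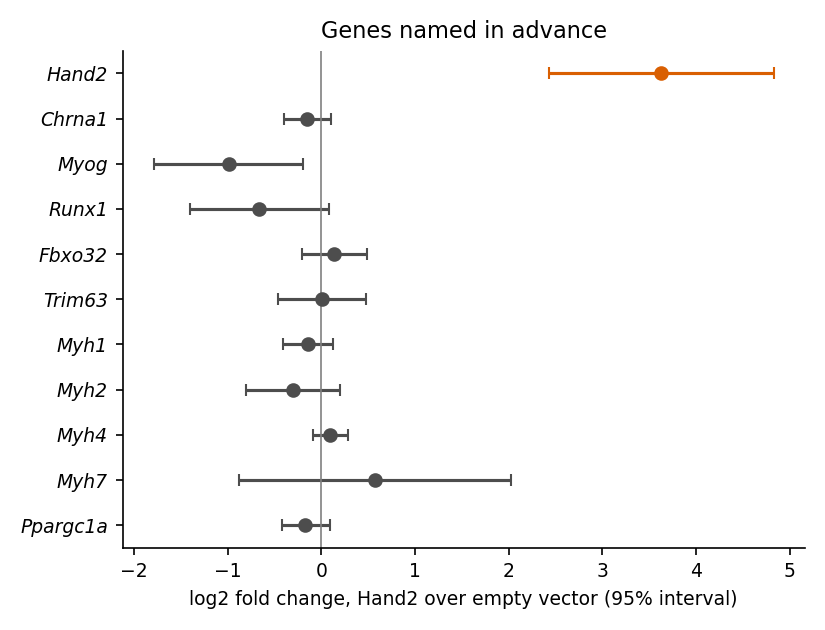
Log2 fold change of Hand2 over empty-vector animals for genes named before the data were examined, with 95% intervals from edgeR's quasi-likelihood fit. Hand2, at 3.63, has the interval farthest from 0, and that of Myog runs from -1.79 to -0.19.

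Immune, matrix and stress lists gave the remaining calls at the preset correlation. Higher were macrophage genes (median 0.24, 19 of 22 members, adjusted p = 2.61e-05; Folr2 0.68 ± 0.25, Csf1r 0.42 ± 0.19, Lyz2 0.35 ± 0.16), MHC class II genes (0.31, 8 of 8, adjusted p = 0.0118) and fibroblast and collagen genes (0.17, 28 of 34, adjusted p = 0.00281; Pi16 0.45 ± 0.21). Their adjusted p was 0.813 with an estimated correlation in each case. Lower were heat-shock genes (-0.13, 26 of 28, adjusted p = 1.46e-09; adjusted p = 0.462 with an estimated correlation), ribosomal-protein genes (-0.07, 78 of 81, adjusted p = 1.59e-21; adjusted p = 0.807 with an estimated correlation), interferon-response genes (-0.22, 35 of 37, adjusted p = 0.0118; adjusted p = 0.813 with an estimated correlation) and proteasome genes (-0.03, 29 of 41, adjusted p = 0.0356; adjusted p = 0.813 with an estimated correlation). The inducible chaperones Hspa1a and Hspa1b, near-identical copies whose reads are uncertain, were at -1.67 ± 0.60 and -1.96 ± 0.66, with SDs in the empty-vector group larger than the means. Without empty-vector replicate 5 the interferon list was called in the opposite direction (median 0.09, adjusted p = 0.0409), and it did not pass without Hand2 replicate 1, 2, 4 or 5 (adjusted p = 0.158, 0.092, 0.0713 and 0.0875) or with an age term (median -0.12, adjusted p = 0.257). The MHC class II list did not pass without Hand2 replicate 7 (adjusted p = 0.205), and the fibroblast and collagen list did not without empty-vector replicate 5 or 10 or Hand2 replicate 5 or 7 (adjusted p = 0.0836, 0.0578, 0.0666 and 0.269). The proteasome list did not pass without empty-vector replicate 2, 5, 7, 8, 9 or 10 or Hand2 replicate 5, 6 or 7 (adjusted p from 0.0607 to 0.211) or without a sex term (adjusted p = 0.0768). In total 10 of 40 lists were called at the preset correlation, 3 higher and 7 lower, and 0 with an estimated correlation or with fry. Without empty-vector replicates 3, 4 and 5 the preset correlation gave 14 calls, 9 higher and 5 lower. The Schwann cell, atrophy, fast-fibre, glycolysis, red blood cell and immediate-early lists were then added, and the denervation and interferon lists dropped out. Random reassignment of the vector within sex called a median of 11 lists at the preset correlation, and 72 of 100 assignments, the real one included, called 10 or more.

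In females the question was whether the 4 Hand2 animals differed from the 5 empty-vector animals. edgeR called 0 genes (824 at an unadjusted p under 0.05), limma-voom called 0 (1198 at an unadjusted p under 0.05), limma on the authors' normalized values called 0 and DESeq2 called 7. Among DESeq2's calls, on the lower side, were Myog (-1.76 ± 0.37, adjusted p = 0.01), the stress factor Atf3 (-3.34 ± 0.73, adjusted p = 0.0238), the muscle repair gene Xirp1 (-1.75 ± 0.39, adjusted p = 0.0239), the dystrophin relative Utrn (-0.28 ± 0.06, adjusted p = 0.0337), Gm13889 (-1.47 ± 0.34, adjusted p = 0.0337), which was named after its values were seen, and Ext1 (-0.34 ± 0.08, adjusted p = 0.0391). Myog averaged 16.1 ± 7.65 CPM in empty-vector females (SD, n = 5) and 4.76 ± 2.0 CPM in Hand2 females (SD, n = 4). Without empty-vector replicates 3, 4 and 5 its log2 fold change in edgeR went from -1.77 to -0.88. The denervation list had a median of -0.24 with 28 of 34 members lower (adjusted p = 3.36e-07; adjusted p = 0.122 with an estimated correlation). Without empty-vector replicates 3, 4 and 5 its median was -0.09 and it did not pass (adjusted p = 0.12). Adjusted over the list alone 4 of its genes passed, Myog, Gdf5, Ankrd1 and Ampd3. Adjusted over the list alone, 5 heat-shock genes also passed, all lower, Hspa1b among them (-2.93 ± 0.81). Hand2 was at 2.47 ± 0.73. Red blood cell markers had a median of -0.98 in females (adjusted p = 0.00177; adjusted p = 0.554 with an estimated correlation), and did not pass without Hand2 replicate 2 (-0.54, adjusted p = 0.187) or without empty-vector replicates 3, 4 and 5 (-0.13, adjusted p = 0.905). At the preset correlation 14 of 40 lists were called, 1 higher and 13 lower, and 0 with an estimated correlation or with fry.

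In males the same comparison set 3 Hand2 animals against 5 empty-vector animals. edgeR called 0 genes (397 at an unadjusted p under 0.05), limma-voom 0 (393 at an unadjusted p under 0.05), limma on the authors' normalized values 0 and DESeq2 1, Hand2. Hand2 was at 4.53 ± 0.70 (interval 3.03 to 6.02, adjusted p = 0.147 in edgeR and 3.08e-05 in DESeq2). The next smallest p values belonged to Stra6, a retinol transporter (1.41 ± 0.32), Rasal2 (0.69 ± 0.17), Aldh1a3, an enzyme of retinoic acid synthesis (1.74 ± 0.45), and Stmn3 (1.77 ± 0.46) on the higher side. On the lower side were Pop7 (-0.58 ± 0.16), Psmd10 (-0.34 ± 0.10), Tial1 (-0.18 ± 0.05), Fam178a (-0.31 ± 0.09) and Commd2 (-0.33 ± 0.10). Without Hand2 replicate 6, whose Hand2 level was 1.25 CPM, edgeR called 2 genes, Hand2 and Aldh1a3 (2.24, adjusted p = 0.00705). The sympathetic-neuron list, which includes Hand2 itself, was called higher in males at the preset correlation (median 0.08, 7 of 9 members higher, adjusted p = 0.00969; adjusted p = 0.406 with an estimated correlation). It did not pass without the gene Hand2 (adjusted p = 0.0995) or without Hand2 replicate 7 (adjusted p = 0.154), 2 fits chosen after the data were seen. Adjusted over the list alone 2 genes passed, Hand2 and the neurotrophin receptor gene Ngfr (2.33 ± 0.60, adjusted p = 1 over all genes). The denervation list had a median of 0.01 in males with 18 members higher and 16 lower. Red blood cell markers had a median of 1.13 in males (adjusted p = 4.7e-05; adjusted p = 0.406 with an estimated correlation), and did not pass without Hand2 replicate 6 (0.34, adjusted p = 0.229). At the preset correlation 15 of 40 lists were called, 11 higher and 4 lower, and 0 with an estimated correlation or with fry.

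The test of whether the Hand2 effect differed between the sexes called 0 genes in edgeR (474 at an unadjusted p under 0.05), 0 in DESeq2, 0 in limma-voom (658 at an unadjusted p under 0.05) and 0 in limma on the authors' normalized values. Myog had an interaction of 1.76 ± 0.59 (male minus female effect, interval 0.50 to 3.02) and Hand2 of 2.06 ± 1.06 (interval -0.20 to 4.31), neither past the threshold. Among the smallest p values were those of Pdcd2 (-0.57 ± 0.12), D3Bwg0562e (-2.86 ± 0.70), Zfp354a (-0.77 ± 0.22) and Mir3064 (-0.88 ± 0.26) on the lower side and of BC026585 (1.86 ± 0.51), Stmn3 (2.37 ± 0.66), Sema4c (0.85 ± 0.24), Evc (0.33 ± 0.09) and the interferon-induced chemokine Cxcl10 (3.99 ± 1.12) on the higher side, all with an adjusted p = 1.

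**Figure D3:**
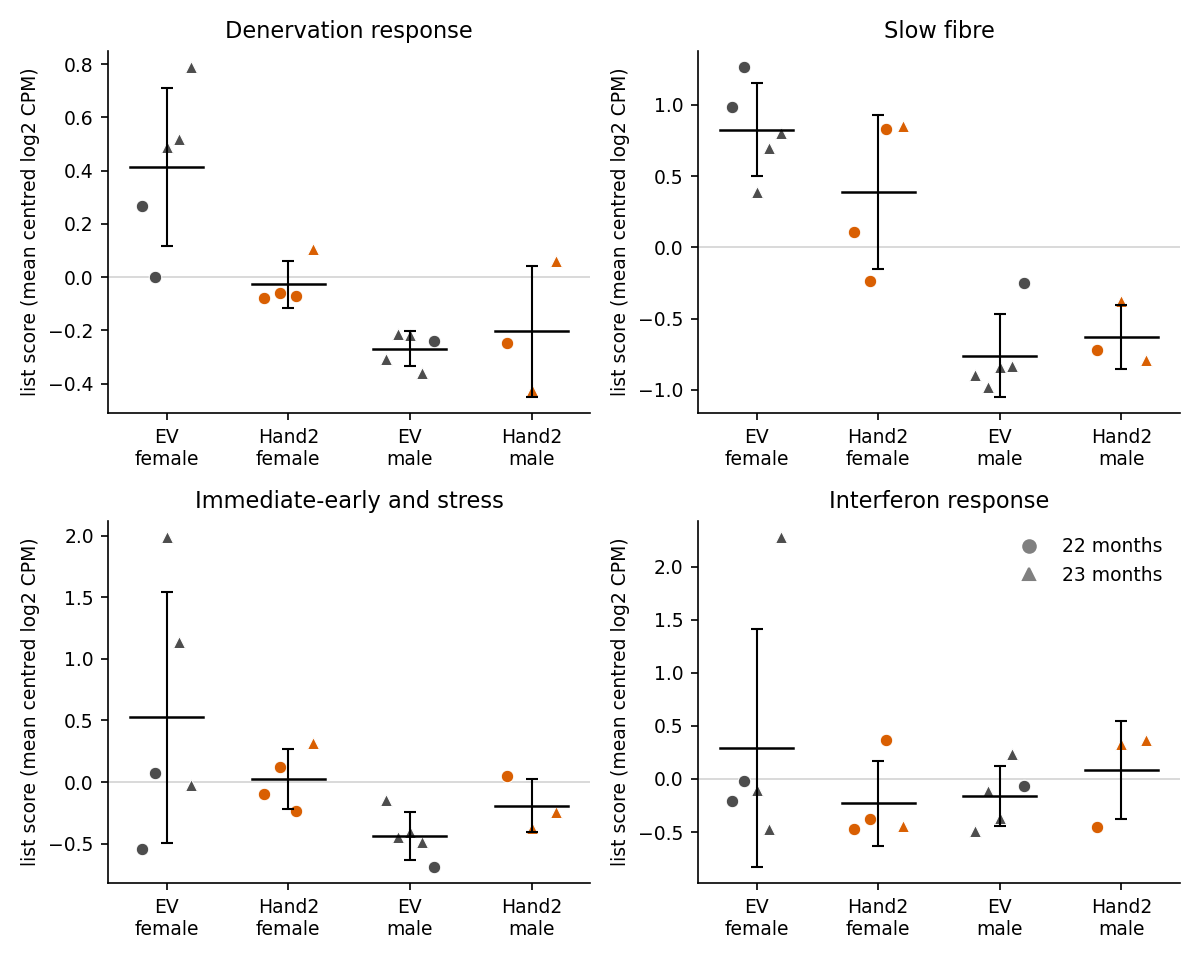
List scores of each library (mean over member genes of log2 CPM centred on the 17 libraries) by vector and sex, with circles for 22 and triangles for 23 months, bars at the mean and whiskers of 1 SD. Empty-vector replicate 5 has an interferon score of 2.28, and the slow-fibre score is above 0 in all 5 empty-vector females and below 0 in all 8 males. That statement leaves out the 4 Hand2 females, in which slow Myh7 ran from 8.34 CPM (replicate 2) to 442 CPM (replicate 5).

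Sex was the larger axis in these muscles. With the vector taken into account, 406 genes were higher and 380 lower in the 8 males than in the 9 females (396 and 343 on autosomes; 3017 at an unadjusted p under 0.05). Upper-quartile scaling gave 514 higher and 270 lower. Of 40 lists 18 were called at the preset correlation, 4 higher and 14 lower, with 0 called with an estimated correlation and 6 with fry. Beyond the Y-linked genes Ddx3y, Eif2s3y, Uty and Kdm5d and Xist, the X-linked genes Eif2s3x (-0.76 ± 0.04) and Kdm5c (-0.87 ± 0.06), known to escape X inactivation, fell. The imprinted long noncoding RNAs Meg3 (-1.48 ± 0.10, adjusted p = 1.17e-08) and Rian (-1.91 ± 0.14, adjusted p = 9.21e-08), neighbours on chromosome 12, were lower in males. Actr3b on chromosome 5 (25760026 to 25850341), a relative of actin-nucleating Arp3, was higher in males at 26.7 ± 2.60 CPM against 3.75 ± 0.992 CPM in females (log2 fold change 2.82 ± 0.13, adjusted p = 5.2e-11).

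Slow-fibre genes were lower in males: 9 of 17 members fell and 0 rose over all genes, and 13 passed adjusted over the list alone. The slow regulatory light chain Myl2 (-2.39 ± 0.32), the slow troponins Tnni1 (-2.77 ± 0.40) and Tnnt1 (-2.21 ± 0.32) and the slow calcium pump Atp2a2 (-1.64 ± 0.26) had adjusted p values of 0.000428, 0.000966, 0.000966 and 0.00168. Myl2 averaged 183 ± 70 CPM in females (SD, n = 9) and 34.9 ± 18 CPM in males (SD, n = 8). The list's median of -1.04 passed at the preset correlation (adjusted p = 5.96e-13) and with fry (adjusted p = 0.000493), with an adjusted p = 0.108 with an estimated correlation, and it was lower within each age (-0.75 at 22 and -1.05 at 23 months). The males of 22 months are empty-vector replicate 10 and Hand2 replicate 4 alone, so that age adds little replication. Of 23 fast-fibre genes, 3 passed, all higher in males, Tpm1 (0.23 ± 0.06), Myoz3 (0.32 ± 0.08) and Myoz1 (0.15 ± 0.04), with an adjusted p = 0.613 for the list with an estimated correlation. These 3 calls ended with an age term (adjusted p = 0.052, 0.0599 and 0.0969). With 1 animal left out, Tpm1 did not pass without Hand2 replicate 7 (adjusted p = 0.052), Myoz3 did not without empty-vector replicate 3, 7 or 8 or Hand2 replicate 3 or 7 (adjusted p from 0.0501 to 0.0542), and Myoz1 passed only without empty-vector replicate 4 or 10 (adjusted p from 0.05 to 0.105 in the other 15 fits).

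**Figure D4:**
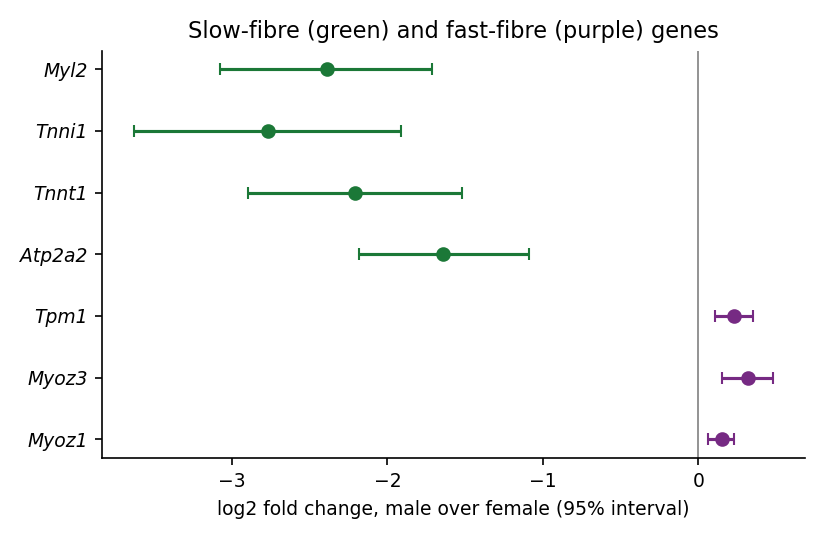
Log2 fold change of males over females for slow-fibre (green) and fast-fibre (purple) genes, with 95% intervals from edgeR's quasi-likelihood fit. The 4 slow-fibre genes lie between -2.77 and -1.64, and the 3 fast-fibre genes between 0.15 and 0.32.

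Denervation-response genes followed the same direction, with 10 of 34 lower in males and 1 higher, led by Igfn1 (-1.73 ± 0.18), Arpp21 (-0.80 ± 0.15), embryonic myosin Myh3 (-0.63 ± 0.14) and the cell-cycle inhibitor Cdkn1a (-1.39 ± 0.30), with an adjusted p = 0.108 for the list with an estimated correlation. The list's median of -0.33 was -0.17 among 22-month and -0.46 among 23-month animals. It was -0.21 without empty-vector replicate 5 and -0.20 without empty-vector replicates 3, 4 and 5, the 3 libraries with the highest list scores (0.49, 0.52 and 0.79), and passed in both at the preset correlation (adjusted p = 3.33e-06 and 0.000115). At that correlation immediate-early genes were also lower in males (-0.56), at -0.15 without those 3 libraries (adjusted p = 0.0188). Red blood cell markers were lower (-0.93), at -0.20 without those 3 (adjusted p = 0.931), and their call ended in 11 of 17 fits with 1 animal left out. At 22 and 23 months the medians were -0.07 and -0.20 for the atrophy, -0.37 and -0.43 for the adipocyte, -0.05 and -0.14 for the growth-factor and -0.03 and -0.13 for the ribosomal-protein list. Of the atrophy list 8 of 32 members fell, among them Mstn, the muscle growth inhibitor myostatin (-0.88 ± 0.16), and Trim63 (-0.94 ± 0.22), whose call ended without empty-vector replicate 7, Hand2 replicate 6 or Hand2 replicate 7 (adjusted p = 0.0503, 0.0506 and 0.0501), with an adjusted p = 0.429 for the list with an estimated correlation. The atrophy score also followed a glucocorticoid-type score, given at the end, that reached 1.2 in females and 0.33 in males. The share of that state in these sex differences was not tested. Adipocyte markers were lower in males for 8 of 24 members, including Pck1 (-1.64 ± 0.27), the adipokine Retn (-1.66 ± 0.32) and the lipid-droplet gene Cidec (-1.60 ± 0.31), with an adjusted p = 0.347 with an estimated correlation. In the growth-factor list 6 genes fell and 1 rose, led by Sesn1, an inhibitor of mTOR signalling (-1.04 ± 0.13), and including Igf2 (-0.35 ± 0.08), which did not pass without empty-vector replicate 7 (adjusted p = 0.0503). The list had an adjusted p = 0.108 with an estimated correlation. Of 81 ribosomal-protein genes 27 fell, by small amounts such as those of Rpl18 (-0.20 ± 0.04) and Rpl7 (-0.15 ± 0.03), with a list median of -0.10 and an adjusted p = 0.429 with an estimated correlation. Dmd, the dystrophin gene on the X chromosome (-0.54 ± 0.05), the synaptic laminin gene Lamb2 (-0.35 ± 0.05) and the muscle fructose bisphosphatase gene Fbp2 (-0.91 ± 0.10) fell. Pgam2 passed on the higher side (0.18 ± 0.05), a call that ended with an age term (adjusted p = 0.0881) and with 1 animal left out in 11 of 17 fits (adjusted p from 0.0576 to 0.0909), all but those without empty-vector replicate 1, 2, 6 or 10 or Hand2 replicate 4 or 5.

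The count of sex calls depended on which animals entered. It was 24 in 22-month animals alone, 413 in 23-month animals alone, 237 without the 4 Hand2 animals whose titles lack a sex letter and 291 without empty-vector replicates 3, 4 and 5, and it fell to 490, 476, 516 and 508 without empty-vector replicate 3, empty-vector replicate 7, Hand2 replicate 6 and Hand2 replicate 7. Without empty-vector replicates 3, 4 and 5, Trim63 (-0.61, adjusted p = 0.14), Cdkn1a (-1.13, adjusted p = 0.131), Myh3 (-0.60, adjusted p = 0.0913), Cidec (-1.41, adjusted p = 0.0893), Rpl7 (-0.15, adjusted p = 0.0781) and Igf2 (-0.40, adjusted p = 0.0516) did not pass. Without the 4 Hand2 animals whose titles lack a sex letter, Trim63, Mstn, Cdkn1a, Cidec, Rpl18 and Rpl7 did not pass (adjusted p = 0.118, 0.0701, 0.128, 0.0621, 0.0863 and 0.0795). In 23-month animals alone Trim63, Mstn and Cdkn1a did not (adjusted p = 0.0846, 0.0566 and 0.173). Tpm1, Myoz3, Myoz1 and Pgam2 passed in neither. In 22-month animals alone the slow-fibre genes Myl2, Tnni1, Tnnt1 and Atp2a2 were at -1.72, -2.80, -2.16 and -1.80 on the log2 scale and did not pass (adjusted p = 0.475, 0.874, 0.881 and 0.883). Nor did Trim63 (-0.47), Arpp21 (-0.43), Myh3 (-0.19), Igf2 (-0.20), Rpl18 (-0.13), Rpl7 (-0.06) and Tpm1 (0.15), whose log2 fold changes were smaller by over 1.5 times than in all animals. Mstn, Sesn1, Dmd, Lamb2, Fbp2, Igfn1, Pck1, Retn, Cidec, Myoz3, Myoz1 and Pgam2 did not pass there either (adjusted p from 0.139 to 0.961). With only empty-vector replicate 10 and Hand2 replicate 4 as males of 22 months, a call lost at that age says little.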

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

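All tests of explanations in this part were chosen after the result was seen. In 7 of 110 sets of group values an animal stood apart from its group, where chance gives about 1 in 20. Empty-vector replicate 5 was highest for the interferon list score (2.28), Chrna1 (63.7 CPM) and Runx1 (27.7 CPM), and empty-vector replicate 4 for Ppargc1a (69.6 CPM). Hand2 replicate 7 was highest for Hand2 (26.3 CPM), Hand2 replicate 5 for Chrna1 (45.5 CPM) and Hand2 replicate 1 for Fbxo32 (1220 CPM).

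The Hand2 effect differed between the sexes for 19 lists at the preset correlation, for 0 with an estimated correlation and for 1, the senescence list, with fry (adjusted p = 0.039). The median differences, male minus female effect, were 2.14 for red blood cell, 0.72 for interferon, 0.57 for immediate-early, 0.52 for MHC class II, 0.43 for CREB target, 0.33 for sympathetic, 0.33 for slow-fibre, 0.30 for denervation, 0.26 for Schwann cell, 0.22 for inflammatory cytokine, 0.21 for fibroblast, 0.16 for fast-fibre, 0.14 for senescence, 0.12 for sarcomere, 0.12 for neuromuscular junction, 0.11 for calcium-handling, 0.08 for basement-membrane, 0.05 for glycolysis and -0.05 for proteasome genes. Of 100 assignments of the vector within sex, the real one included, 4 called as many lists, with 22 the highest of the others. The assignments were drawn at random, so a share this near 5% is imprecise. It was not corrected for the other counts tested in this way, and chance is not firmly excluded for that count.

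Several of these differences rest on few animals. Without empty-vector replicate 5 the interferon difference was 0.21 and passed (adjusted p = 0.0237). Without empty-vector replicate 3 the immediate-early difference was 0.29 and passed (adjusted p = 0.018), and the CREB-target difference was 0.18 and did not (adjusted p = 0.144). Without empty-vector replicates 3, 4 and 5 those 2 were at -0.08 and -0.15 (adjusted p = 0.713 and 0.867), and in all 10 of the 19 calls ended, that of the denervation list (0.10, adjusted p = 0.161) and the Schwann cell list (0.08, adjusted p = 0.515) among them. With 1 animal left out 9 of the 19 lists passed in all 17 fits. Among those 9 the median was 0.06 for calcium-handling genes without Hand2 replicate 2 and 0.07 for sarcomere genes without empty-vector replicate 2, and it was 0.35 for senescence genes without empty-vector replicate 1. The sympathetic call ended without Hand2 replicate 7 (0.25, adjusted p = 0.246), Hand2 replicate 3 or 4 or empty-vector replicate 1, 3 or 10. MHC class II did not pass without empty-vector replicate 5, 6 or 10 or Hand2 replicate 2, 5 or 7 (adjusted p up to 0.31), and inflammatory cytokines did not without empty-vector replicate 2, 5 or 6 or Hand2 replicate 3 or 7 (up to 0.309). Fibroblast genes did not without empty-vector replicate 1, 3, 4 or 10 or Hand2 replicate 3, 4 or 7 (up to 0.458), and basement-membrane genes did not without empty-vector replicate 1, 2, 4 or 10 or the same 3 Hand2 animals (up to 0.343). Glycolysis passed only without empty-vector replicate 1, 2, 8 or 9 or Hand2 replicate 2, 4 or 5. Proteasome genes did not pass without empty-vector replicate 1 or 3, CREB targets without Hand2 replicate 4, slow-fibre genes without empty-vector replicate 2 (adjusted p = 0.0507, while their median was 0.65 without Hand2 replicate 4) and neuromuscular-junction genes without Hand2 replicate 7 (adjusted p = 0.0768).

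The lower denervation list in Hand2 females was weighed. The list score averaged -0.03 in 4 Hand2 and 0.41 in 5 empty-vector females, a difference of -0.44 (SD within groups 0.23, exact permutation p = 0.0317, not corrected for the choice among 40 lists). It was -0.38 without the immediate-early-high empty-vector replicates 3 and 4 (exact p = 0.0571) and -0.35 without the interferon-high replicate 5 (exact p = 0.0571). Without all 3 it was -0.16 (exact p = 0.133, 2 empty-vector animals left, smallest possible p 0.0667), and within 22 months -0.20 (exact p = 0.1, the smallest possible). All 4 differences exceed the SD of the animals left (0.26, 0.18, 0.12 and 0.11); an exact p under 0.05 was also asked for before an explanation was set aside, a requirement added after the differences were seen. The last 2 sets are too small to give such a p, so they decide nothing either way. Stress or interferon responses in those 3 animals, their age of 23 months and an effect of the vector in females cannot be told apart, because all 3 are the 23-month empty-vector females and only 1 Hand2 female is of that age. Title form cannot be separated either. The Hand2 females of 22 months all lack the sex letter in their titles, and every empty-vector female has it.

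Other groupings bear on each count of calls. Where the real count of genes is 0, any split reaches it (100 of 100 for the vectors, for the sex difference and in females, 56 of 56 in males), which says nothing about chance; the highest of the others called 1, 7, 108 and 0 genes. For the vectors the real 10 lists were reached by 72 of 100, with 19 the highest, so chance is not excluded. In females 21 of 100 splits reached the real 14 lists, with 22 the highest, so it is not excluded there either. Any gene was called in 8 of those 100 splits. The split with 108 genes, picked as the highest, set empty-vector replicates 1 and 2 and Hand2 replicates 1 and 5 against the other females. Whether it reflects a structure among the females other than the vector was not tested. In males 3 of 56 splits reached the real 15 lists, with 15 the highest of the others, so chance is not excluded at 5%. For the sexes 1 of 100 assignments within vector, the real one, reached 786 genes, with 345 the highest of the others, so chance is excluded; 6 of 100 reached the real 18 lists, with 20 the highest, so for lists it is not.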

How the results depend on the processing

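The limma fit on the authors' normalized values, the fits without empty-vector replicates 3, 4 and 5, the single-age and title-form fits of the sexes and the lists within and between the sexes with an animal left out were chosen after seeing the data. Leaving out each animal in turn gave 0 to 1 calls for the vectors, 0 to 1 in females (1 without Hand2 replicate 3, and Colq without Hand2 replicate 5), 0 to 2 in males, 0 for the sex difference, 476 to 952 for the sexes and 7 to 14 gene lists. The 0 of each vector comparison in edgeR also held under other scalings, filters, an age term and a 10% threshold, and that of the vectors with 1 surrogate variable, which was run for that comparison alone. DESeq2 called 1, 7, 1 and 0 genes for the vectors, in females, in males and for the sex difference, and 1276 for male versus female; with the 4 Hand2 animals lacking a sex letter as the only Hand2 animals 1 gene, Hand2, was called. At 10% male versus female gave 1334 calls, and it gave 24 and 413 within 22 and 23 months, 237 without those 4 animals and 291 without the 3 empty-vector animals, where fewer animals enter. An age term gave 530, of which 483 were among the 786. For the vectors gene lists gave 0 calls with an estimated correlation and 0 with fry. The log2 difference of Hand2 was 3.08 and 1.70 with 0.01 and 1 CPM added in place of 0.1 (2.78), settings chosen after seeing the data; the exact p cannot move, since the groups do not overlap. The cause was not tested for the other changes.

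Reversed directions in the comparison of vectors, none of them called in either fit unless stated, were as follows. Myh7 was at -0.78 in limma-voom, -1.18 at 22 months, -0.64 with those 4 Hand2 animals, -0.22 in females alone, -0.23 on the authors' normalized values and -0.24 to 0.85 with an animal left out. Trim63 was at -0.45 at 23 months, -0.38 without those 4 animals, -0.17 in females alone and -0.12 to 0.16 with an animal left out. Fbxo32 was at -0.11 at 23 months, -0.08 without those 4 and -0.05 to 0.23 with an animal left out. Ngfr was at -0.35 at 22 months and at -0.08 with those 4 as the only Hand2 animals. The interferon list, called at the preset correlation, had a median of 0.067 without empty-vector replicates 3, 4 and 5 and from -0.325 to 0.088 with an animal left out, and was called higher without replicate 5; the change without replicate 5 follows from that animal's high score. In females without empty-vector replicates 3, 4 and 5 CREB targets were at 0.09 and immediate-early genes at 0.32, the latter called, and the sex differences of those lists were at -0.15 and -0.08. With an animal left out interferon genes in females were at -0.71 to -0.03, where without empty-vector replicate 5 the test leaned higher and did not pass, and oxidative phosphorylation in males was at -0.07 to 0.03, called higher without empty-vector replicate 10. Low counts limit Th and Dbh, which entered only a fit with no low-count filter, chosen after seeing the data, where neither passed. Scaling moved the median of all genes by at most 0.06 on the log2 scale.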

Other observations

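The comparison of title forms and the glucocorticoid list were chosen after seeing the data; the tests of the title-form genes against age, library size and the share of the largest genes in the empty-vector animals were written before their results were seen. Within the Hand2 group the 3 animals whose titles carry a sex letter differed from the 4 without by 71 genes (35 higher, 36 lower, of 13465 tested with sex as a term in edgeR). Among the genes lower in the lettered animals, chosen after their values were seen, were the lipase gene Pnpla2 (-0.60 ± 0.08), the fatty-acid enzymes Acot2 (-1.33 ± 0.16) and Mlycd (-0.66 ± 0.09), glutamine synthetase Glul (-1.33 ± 0.14, 573 ± 102 CPM in 3 against 1510 ± 209 CPM in 4) and the clock output gene Dbp (-0.88 ± 0.11). Higher were Fam53b (0.87 ± 0.08), Mkl1 (1.56 ± 0.18), Actb (0.50 ± 0.08) and Srebf2 (0.72 ± 0.11).

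Of 34 splits of the Hand2 animals into 4 and 3 that could be fitted, 1, the real one, called as many genes, and the highest of the others called 1. No smaller share is possible with 34 splits, and the comparison was chosen after seeing the data. Chance is therefore unlikely but not firmly excluded. The lettered animals are 23 months old and the others 22 months. Age is a candidate explanation, and the empty-vector animals cannot decide it. There the 71 genes differed between 7 animals of 23 and 3 of 22 months by a median of -0.12, signed by the title-form difference. That is the opposite way, with 25 of 71 the same way and a spread of 0.14 between reassigned animals (exact permutation p = 0.325). The title-form difference had a median size of 0.72. The 23-month females there are empty-vector replicates 3, 4 and 5 alone, with glucocorticoid-type scores (given below) of 0.8, 1.2 and 0.9. The lettered Hand2 animals had scores of -0.73, -0.59 and -0.81. A state shared by those empty-vector females could hide or reverse an effect of age, and its share was not tested. Library measures also separated the sets. The lettered libraries held 19181208 to 22051694 counts with 13.9% to 14.3% of them in the 10 largest genes, and the others 25410180 to 30715990 with 12.3% to 13.3%. The slope of the mean signed value of the 71 genes on library size among the 10 empty-vector libraries, with sex as a term, gave a difference between title forms of -0.08 ± 0.24 (SE, permutation p = 0.711), where 0.87 was seen. This argues against library size as the whole cause, as far as a slope over 22296800 to 30942818 counts extends to the smaller lettered libraries. For the share of the 10 largest genes the slope gave 0.19 ± 0.24 (permutation p = 0.417), too imprecise to decide. A difference between batches of animals, library preparation, feeding state or time of day at collection remains open and was not tested. All 4 animals without the letter carry the Hand2 vector and all 10 empty-vector titles carry it, so title form is partly confounded with vector, and this structure could affect the spread or the mean of the Hand2 group; the share it contributes was not tested.

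A hypothesis for the spread of the atrophy list between animals is a glucocorticoid-type response. It came from genes seen to separate these animals on the first principal component, some of them atrophy genes, so the test is not independent of what prompted it. A list of 17 glucocorticoid-responsive genes, 16 of them measured and absent from the atrophy list, was scored in each animal; some of its genes also respond to fasting or the clock, and many atrophy genes are themselves glucocorticoid targets. Its score correlated with the 32-gene atrophy score over all 17 animals (Pearson r = 0.94, Spearman rho = 0.917, permutation p = 1e-05 for each, the smallest 100000 resamples can give, adjusted p = 3e-05 over 6 relations). Without the 2 animals farthest from the median r was 0.916. It was 0.952 in empty-vector, 0.929 in Hand2, 0.959 in female and 0.935 in male animals, with exact or permutation p between 7.72e-05 and 0.00258. The glucocorticoid score ran from -0.8 to 1.2 in females and from -0.93 to 0.33 in males. The lower atrophy genes in males are therefore not separated from it. Random lists of 16 genes matched on expression reached r = 0.73 at their 95th percentile, so broad covariation is high, and 2 of 10000 reached 0.94. Animals differing in a shared hormonal or feeding state at collection could give this, and it does not distinguish the hormone from fasting. Its link to single atrophy genes was not tested. Trim63 was highest (863 CPM) in empty-vector replicate 4, which had the highest glucocorticoid score (1.2). Fbxo32 was at 573 CPM there, and was highest (1220 CPM) in Hand2 replicate 1, with a score of 0.34.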
